A study of Mus musculus with 8 samples.

How the data were processed

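The series holds 8 Repli-seq libraries of mouse embryonic stem cells, from cells given auxin for 2 days or left without it, with 2 replicates per group and an early and a late S-phase library for each replicate. Per the labels' protocols, cells were pulsed with BrdU for 2 hours, cells were sorted into early and late S-phase fractions on propidium iodide, and BrdU-labelled DNA was immunoprecipitated and made into Illumina libraries. Per the submitters' processing notes, Bowtie2, SAMtools and bedtools were used with the mm10 build; their versions, settings and roles are not given in the sources used here. Trimming, filters on mapping quality and duplicates, smoothing and the formula that joins the early and late library are likewise not given in the sources used here. How far neighbouring windows share reads is therefore unknown.

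The authors deposited timing scores in a table with a column for each replicate of each group, and each score is per window of a 6-kb grid (88.2% of steps are 6 kb). The columns were quantile normalized by the authors, per the file headers' names and the values: sorted, all 4 columns are identical, with a mean of -0.045, an SD of 2.1, a minimum of -10.48 and a maximum of 23.35. Quantile normalization forces the same distribution on every profile, so a genome-wide shift or a change in overall contrast cannot be seen in these scores. The direction (higher is earlier) follows from the authors' early-to-late list, in which scores are lower with auxin. The authors also deposited 2 lists of regions, each with the profiles' scores, absolute differences between and within groups, and a q-value whose test is not given in the sources used here. Each region spans 23 windows, and its deposited scores equal the mean of those windows. The q-values were not used. Columns were matched to groups and replicate numbers by name. Depth per profile is unknown, since no file gives read counts, and no interval was set on that basis.

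Scores were averaged in 48080 bins of 50 kb, of which 5370 (11.2%) hold fewer than 3 windows. Auxin was compared with control by limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, with treatment as the only term, 2 residual degrees of freedom and Benjamini-Hochberg adjusted p under 0.05. Bins that also differed by 1 or more were counted apart. Gene coordinates came from a RefSeq table of GRCm38.p6, which has the coordinates of mm10. Of 21631 protein-coding genes, 21078 had a value: the mean of the windows over the gene body, or for 1063 genes the nearest window within 50 kb. Genes that overlap no window or few windows have less certain values, and members of near-identical families (olfactory and vomeronasal receptors, zinc finger genes) can share reads. The 16 gene lists were tested with camera, two-sided, with the inter-gene correlation estimated, and adjusted over the lists; H19, Meg3, Kcnq1ot1 and Airn are not protein-coding and were not measured.

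Timing classes were set on the mean of all 4 profiles, early above 0.5, late below -0.5 and middle between. Transitions were local maxima of the absolute slope of that mean over 200 kb, where timing changed by 1 or more within 1 Mb, and each profile's slope was signed by the mean. Group differences in class medians and median slopes were tested by exact permutation of the 4 profiles, two-sided. The authors' regions were set against called bins by an overlap of at least 50% of a bin. SDs are over 2 profiles.

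Named genes follow a rule fixed before the data were examined, as were the tests, the gene lists and the alternatives unless stated otherwise: the 5 regions with the largest difference in each list with their genes; the 8 genes with the largest difference in each direction, apart by 1 Mb or more, that pass the test, or else the largest whose groups do not overlap; Dppa2, Dppa4, Ctcf, Pou5f1, Nanog, Sox2 and Rif1; and the 2 members with the largest difference of each list.

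The fits were tested on simulated data with 50 shifted bins or genes per size. The simulated noise was independent between bins or genes, and its spread was drawn the same way whatever the score or number of windows. The shares and false calls below therefore need not hold for the data, least of all for the trended, robust fit. Of bins shifted by 1, 1.5 and 2, the fit over all bins recovered 0%, 44% and 78%, and the fit over bins with at least 3 windows 8%, 66% and 98%. For genes the shares were 0%, 6% and 54%, and 16%, 80% and 96% with at least 3 windows. No bin or gene shifted by 0.5 was recovered in any of these 4 fits, and unshifted bins or genes were called 4 and 2 times for bins and 0 and 4 times for genes. With the trended, robust variance over all bins the shares were 2%, 4% and 44% with 1 false call, and over bins with at least 3 windows 10%, 70% and 88% with 7; over all genes they were 0%, 22% and 64% with 0, and over genes with at least 3 windows 12%, 76% and 100% with 5. In camera, a simulated list of 26 genes shifted by 0.5 had an adjusted p of 0.184 with an estimated correlation and 2.378e-15 with the preset one. Neither called any of 15 unshifted lists. The genes of these lists varied independently, so the simulation cannot show how often either setting calls lists of correlated genes by mistake.

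Alternatives included single windows, 100-kb bins, other scaling, autosomes only, a trended and robust variance, each replicate left out, a replicate block, other limits for classes and slopes, other list tests, and, added after seeing the data, bins and genes with at least 3 windows, the window nearest the middle of a gene, transitions picked in other profiles, and the late-to-early list without 1 extreme window. Ranges were handled with GenomicRanges 1.54.1 and tables with the R package data.table, version 1.17.8; figures were drawn with matplotlib 3.10.9 in Python 3.11.15.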

Results

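Replication timing was profiled in E14Tg2a mouse embryonic stem cells in which CTCF carries an auxin-inducible degron. CTCF is a zinc finger protein that binds insulator sites and, together with cohesin, anchors chromatin loops. Cells were given the auxin indole-3-acetic acid at 500 µM for 2 days, and cells without auxin served as controls. After a 2-hour BrdU pulse, early and late S-phase cells were sorted and their labelled DNA was sequenced separately. The 8 libraries make 4 timing profiles, 2 with auxin and 2 without, because each replicate joins an early and a late library. Each profile holds a score at 316864 windows on a 6-kb grid over 20 chromosomes of the mm10 build, and a higher score means earlier replication. The log base and scale of the score are not given in the sources used here, so differences are in score units, with a genome-wide SD of 2.1. The deposited tables hold no read counts, so the depth of each profile is unknown. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. CTCF protein was not measured in the files used here, so the extent of its loss could not be checked.

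The comparison of auxin with control cells asks whether acute loss of CTCF moves the time at which loci replicate. The series holds no cells without the degron that were given auxin, so effects of auxin itself cannot be told apart from those of CTCF loss. In bins of 50 kb that hold at least 3 windows, 435 bins moved later and 272 moved earlier with auxin, out of 42710 (limma, Benjamini-Hochberg adjusted p under 0.05). The longest run of later bins spanned 550 kb on chromosome 2 (65300001 to 65850000) across Scn3a and Scn2a, which encode voltage-gated sodium channels, and fell by 1.51 on average. Other long runs that moved later covered Cyria on chromosome 12 (12050001 to 12500000), with a mean difference of -1.47, and the bone morphogenetic protein receptor gene Acvr1 on chromosome 2 (58450001 to 58750000), with -1.41. The longest run of earlier bins, 400 kb on chromosome 1 (77450001 to 77850000), covered the ephrin receptor gene Epha4 and rose by 1.53. Runs around Peli1 on chromosome 11 (20850001 to 21150000) and the NMDA receptor subunit gene Grin2a on chromosome 16 (9350001 to 9650000) rose by 1.32 and 1.18.

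The called bins formed 395 runs with a median length of 50 kb, 175 of them earlier (13.6 Mb) and 220 later (21.75 Mb). Runs that moved later also covered the Wnt transcription factor gene Lef1 on chromosome 3 (130900001 to 131250000), with a control mean of 0.10 ± 0.015 and an auxin mean of -1.26 ± 0.041 (SD, n = 2 each). On chromosome 12 (57350001 to 57600000), the run over the pioneer factor gene Foxa1 went from -0.03 ± 0.049 to -1.40 ± 0.15. At Hhip, the gene of a hedgehog-binding membrane protein on chromosome 8 (79800001 to 80100000), the run went the other way, from -0.38 ± 0.019 to 0.80 ± 0.0038. Bins of middle timing were called most often, with 1.34% earlier and 2.23% later, against 0.631% and 0.743% of early bins and 0.473% and 0.951% of late bins. Of the bins with at least 3 windows, 876 differed by 1 or more between the group means, while 406 did so between the auxin replicates and 725 between the control replicates. Over all 48080 bins the order differed, with 983 between the group means, 751 between the auxin replicates and 1317 between the control replicates. Noise moves a difference between means of 2 profiles less than a difference between single profiles. The group and replicate counts are therefore not on the same footing.

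The limit of 3 windows was chosen after seeing the data, and the runs named here were picked after their values were seen. Over all 48080 bins, the fit fixed beforehand called 1 bin, on chromosome X (126200001 to 126250000, 1 window). Its window, at 126240000, held the maximum score of 23.35 in both auxin profiles, against -2.94 and -10.48 in the controls. That call thus rests on 1 extreme window. In this limma fit 8898 bins had an unadjusted p under 0.05. The same fit called 3164 single windows, and moderation with a mean-dependent trend and robust variances called 3853 bins. The windows split into 1159 earlier and 2005 later, while the trended, robust fit split more evenly, into 1826 earlier and 2027 later bins (52.6% later), or 2209 and 2417 in bins with at least 3 windows, against 61.5% later among the 707. Of the 707 bins called with at least 3 windows, 703 were also called in the same direction by the trended, robust fit, and 110 by the fit with a replicate block, both over all bins.

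**Figure D1:**
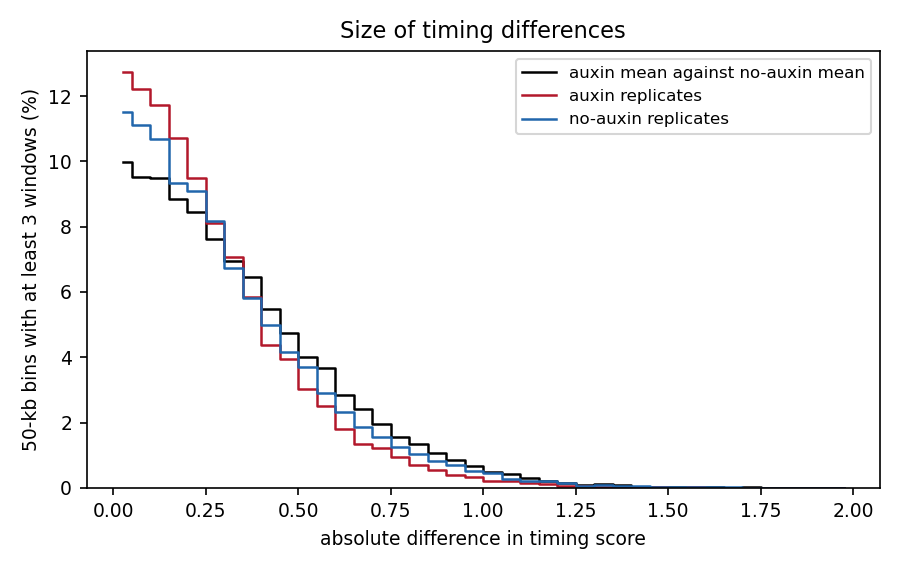
Share of 50-kb bins with at least 3 windows (y axis, %) by the absolute difference in timing score (x axis, score units), for the auxin mean against the no-auxin mean (black) and for the replicates of each group (red, auxin; blue, no auxin); values of 2 or more are in the last step. At 1 or more, the group comparison holds 2.05% of bins, the auxin replicates 0.951% and the control replicates 1.70%. The group comparison is between means and the replicate comparisons are between single profiles, which noise moves more.

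The authors deposited a list of regions that replicate later with auxin and a list of those that replicate earlier, chosen on these same samples. The early-to-late list has 63 regions in 40 loci on 14 chromosomes, with 84 protein-coding genes, and the late-to-early list has 22 regions in 15 loci on 9 chromosomes, with 29 genes. Over the early-to-late regions the mean score went from 0.46 ± 0.013 in control profiles to -0.86 ± 0.032 with auxin, and over the late-to-early regions from -0.57 ± 0.0028 to 0.67 ± 0.00052 (SD, n = 2 each). Together they span 14.4 Mb, of which a region on chromosome X takes 2952 kb. Their windows make up 0.617% of all windows, with a window shared by adjoining regions counted in each. All 4 profiles kept the groups apart in each of the 85 regions, which is no independent test, since the lists were drawn from these profiles.

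The largest early-to-late difference, -1.85, lay over the sodium channel gene Scn3a (chromosome 2, 65466000 to 65598000), where the control mean was 0.79 ± 0.059 and the auxin mean -1.07 ± 0.11 (SD, n = 2). Next came Cyria, a gene linked to Rac signalling, with -1.79 (chromosome 12, 12228000 to 12360000). A gene-dense region on chromosome 3 (137820000 to 137952000) that holds the H2A.Z histone gene H2az1, Dnajb14, the Ragulator gene Lamtor3 and Dapp1 stood at 2.61 ± 0.056 in control and 0.94 ± 0.25 with auxin. The regions over the potassium channel gene Kcnt2 (chromosome 1, 140184000 to 140334000) and over Gm46977 and the ETS repressor gene Etv6 (chromosome 6, 133938000 to 134076000) both differed by -1.63.

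Among late-to-early regions, the largest difference was 1.67, in a stretch of chromosome 1 without a protein-coding gene (77610000 to 77742000), from -1.41 ± 0.098 to 0.26 ± 0.0097 (SD, n = 2). The adjoining region over Epha4 (77472000 to 77610000) differed by 1.56. Peli1, a ubiquitin ligase gene on chromosome 11 (20964000 to 21096000), lay in a region with 1.48, and Bpifa6 and Bpifa2 on chromosome 2 (153972000 to 154104000) in a region with 1.36. A region of 2952 kb on chromosome X (124134000 to 127086000), which holds the vomeronasal receptor gene Vmn2r121, 4932411N23Rik and Gm382, differed by 1.60. That value rests on the window at 126240000, with 23.35 in both auxin profiles against -2.94 and -10.48 in the controls, and without it the difference is 0.30. Another late-to-early region, on chromosome 11 (73872000 to 74052000), holds 7 olfactory receptor genes, among them Olfr139, and went from -3.03 ± 0.13 to -1.93 ± 0.15.

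In control cells, 27 of the 63 early-to-late regions were early, 23 middle and 13 late, and of the 22 late-to-early regions 5 were early, 7 middle and 10 late. The gene bodies in the lists went the same way as their regions in 84 of 84 measured genes of the early-to-late list and 28 of 28 of the late-to-early list. Since the regions were chosen for differing in these same profiles, this count and the overlaps with called bins that follow were largely set by that choice. Bins covered at least 50% by a region were called in the region's direction for 154 of 174 early-to-late bins and 50 of 64 late-to-early bins, when bins with at least 3 windows were tested. With all bins in the test, 0 of 174 and 1 of 68 covered bins passed. The 1 that passed is the bin with the extreme window on chromosome X.

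**Figure D2:**
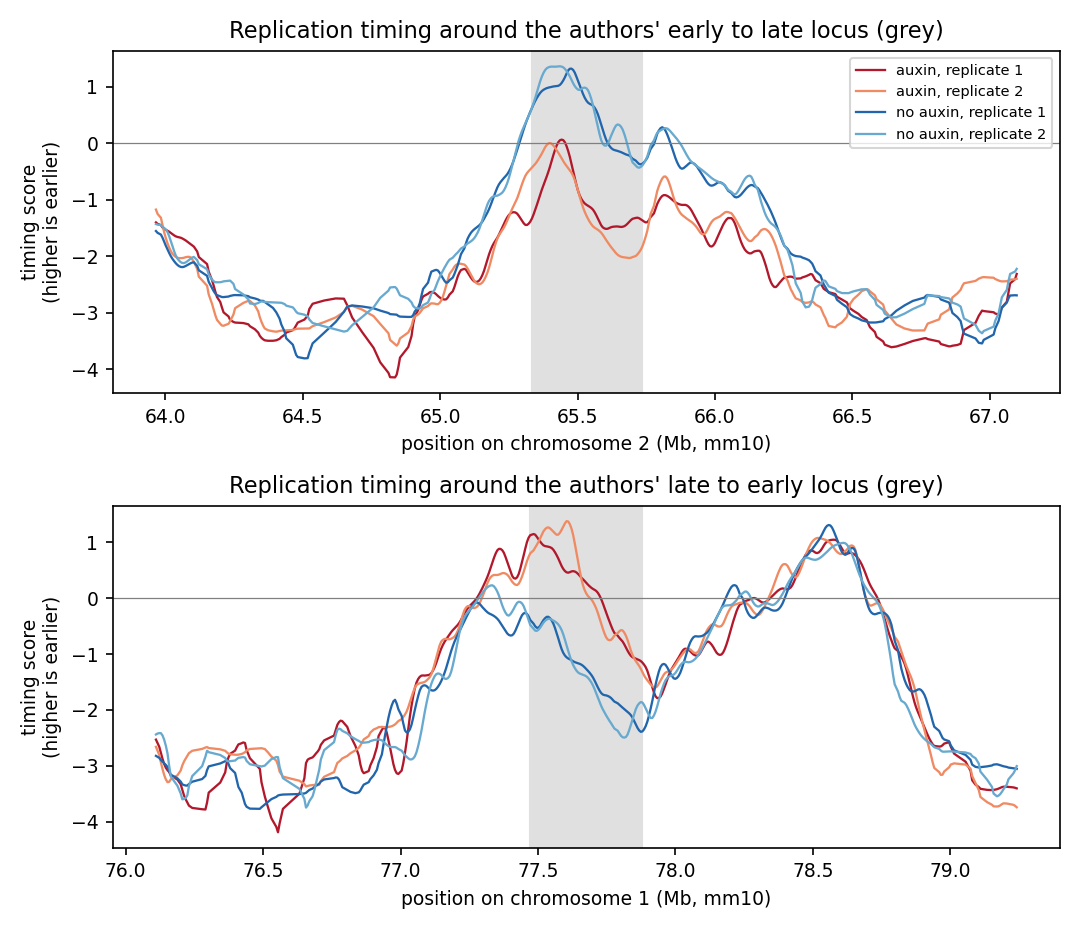
Timing score (y axis, score units, mean of 5 neighbouring windows) against position (x axis, Mb, mm10) for the 4 profiles, around the authors' early-to-late locus at Scn3a on chromosome 2 and their late-to-early locus at Epha4 on chromosome 1, with the loci in grey. The red and orange auxin lines run below the blue control lines in the upper locus (mean difference -1.62) and above them in the lower locus (mean difference 1.51).

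**Figure D3:**
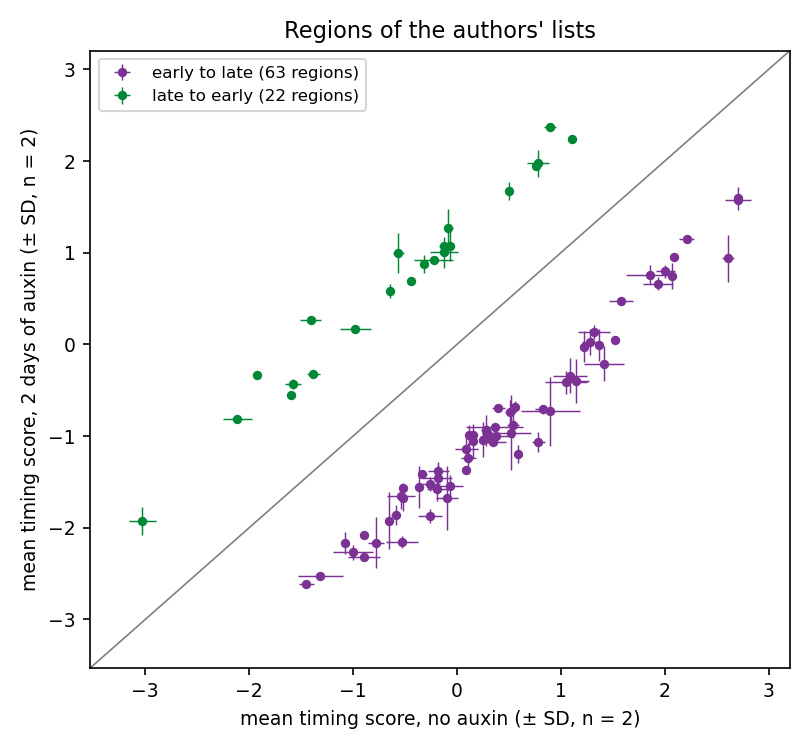
Mean timing score with auxin (y axis) against without auxin (x axis) in each region of the authors' lists, in score units, with bars for the SD of 2 profiles and a diagonal line of equal values. The 63 early-to-late regions (purple) lie below the line by 1.05 or more and the 22 late-to-early regions (green) above it by 1.04 or more.

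For single genes, the timing score of 21078 protein-coding genes was averaged over the gene body, or taken from the nearest window for 1063 of them. Among genes with at least 3 windows, the largest difference toward later replication, -1.89, was at Gm46977 at the Etv6 locus (4 windows), followed by Scn3a (1.00 ± 0.0073 in control, -0.84 ± 0.13 with auxin, 19 windows), Lamtor3 (2.72 ± 0.030 against 0.88 ± 0.20, 3 windows) and Cyria (0.48 ± 0.012 against -1.24 ± 0.19, 21 windows; SD, n = 2 throughout). Dusp26, the gene of a phosphatase on chromosome 8, differed by -1.74, and Akap14, 4930595M18Rik and Loxl2 by -1.91, -1.82 and -1.65. Toward earlier replication, the largest differences were at DXBay18 (2.19), Dcaf12l2 (2.01), Gm4027 (1.56), Selenov (1.51), Gm5954 (1.51), Cldn34c1 (1.47), Dmrtc1c1 (1.46) and Ctag2l2 (1.41). Each of these genes holds at most 2 windows. DXBay18, Dcaf12l2, Gm5954 and Cldn34c1 overlap no window and take the value of the nearest one within 50 kb. Among the later genes, 4930595M18Rik also overlaps no window, Akap14 and Loxl2 overlap 1 each, and Dusp26 overlaps 2. Leaving out a single profile moved Gm5954 to 0.65 (without auxin replicate 1) or 2.37 (without auxin replicate 2), Cldn34c1 to 0.57 or 2.36 (without control replicate 1 or 2), Ctag2l2 to 0.91 (without control replicate 2) and Loxl2 to -1.06 (without control replicate 1). No gene passed an adjusted p of 0.05 in limma, neither over all genes nor among the 12984 with at least 3 windows. Among the latter, the smallest adjusted p in limma was 0.0755. Over all genes, 3610 had an unadjusted p under 0.05, and the smallest adjusted p was 0.172. With a trended, robust variance, limma called 1119 genes, 424 earlier and 695 later, including all 16 of the genes named here except Gm5954 and Cldn34c1.

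The core pluripotency genes Pou5f1, Nanog and Sox2 replicated early in both groups. Pou5f1 scored 2.92 ± 0.40 in control and 3.20 ± 0.067 with auxin, Nanog 2.77 ± 0.51 and 2.97 ± 0.13, and Sox2 2.43 ± 0.34 and 2.17 ± 0.21 (SD, n = 2). None of the 26 pluripotency genes passed in limma (2 at an unadjusted p under 0.05, and 2 with a trended, robust variance). Over all 21078 genes, the matching limma counts were 3610 and 1119. The counts of this and the later lists are to be read against those shares. The largest differences among the pluripotency genes were at the orphan nuclear receptor gene Nr0b1 (-1.09) and the DNA demethylase gene Tet2 (-0.95). Dppa2 and Dppa4, neighbours on chromosome 16 that encode DNA-binding proteins of early embryos, differed by -0.14 and -0.12 (limma adjusted p of 0.796 and 0.842). With control replicate 2 left out, both signs turned (0.061 and 0.17), and with control replicate 1 left out those of Nanog (-0.16) and Pou5f1 (-0.0052) did, while Sox2 stood at -0.018. Without control replicate 2, these 3 genes differed more, with Nanog at 0.56, Pou5f1 at 0.57 and Sox2 at -0.50.

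The gene of the factor that carries the degron, Ctcf, stood at 4.01 ± 0.30 in control and 3.53 ± 0.12 with auxin (SD, n = 2, limma adjusted p of 0.345). Of 18 CTCF and cohesin genes, 0 passed in limma (2 at an unadjusted p under 0.05, 0 with a trended, robust variance). The largest differences were at the meiotic cohesin gene Smc1b (-0.76) and the cohesin acetyltransferase gene Esco2 (0.62). Without control replicate 2, Ctcf differed by -0.26 and Smc1b by -0.44. Among 28 genes of origins and timing control, with 0 past the limma threshold (6 unadjusted, 1 trended and robust), Rif1, which encodes a regulator of timing, stood at 2.14 ± 0.14 and 1.48 ± 0.17. The replication inhibitor gene Gmnn differed by -0.90 and the origin recognition gene Orc6 by 0.70.

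Several clusters with known CTCF sites or monoallelic expression were examined as groups. Of 28 measured imprinted genes, 4 passed when adjusted over the list alone and 0 over all genes (6 unadjusted; 2 earlier and 2 later trended and robust). The 4 were Dio3 (1.44 ± 0.028 to 2.42 ± 0.082), the signalling adaptor gene Grb10 (1.85 ± 0.15 to 0.91 ± 0.18), its neighbour Ddc (2.30 ± 0.26 to 1.46 ± 0.0078) and Mest (0.02 ± 0.12 to 0.86 ± 0.22; SD, n = 2). The 57 clustered protocadherin genes had a median difference of -0.07 and none passed in limma (0 at an unadjusted p under 0.05, 0 trended and robust), with Pcdhb4 and Pcdhb3 at -0.42 each. Those values rest mainly on auxin replicate 2, without which they were -0.065 and -0.057, against -0.77 and -0.78 without auxin replicate 1. The 39 Hox genes had a median difference of 0.19 and none passed (3 unadjusted, 0 trended and robust), with Hoxb2 at 0.88 and Hoxb3 at 0.84. The Hox median was -0.04 without auxin replicate 1, 0.48 without auxin replicate 2, 0.015 without control replicate 1 and 0.29 without control replicate 2, and Hoxb3 stood at 0.23 and 1.45 without control replicate 1 and 2.

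Of 22 neural lineage genes, 5 passed when adjusted over the list alone and 0 over all genes (8 unadjusted; 2 earlier and 2 later trended and robust). The microtubule gene Dcx (-1.79 ± 0.17 to -0.52 ± 0.53) and the growth factor gene Ptn (-1.41 ± 0.051 to -0.46 ± 0.12) were earlier with auxin, while the transcription factor genes Sox3 (difference of -1.07) and Zic1 (-0.90) and the glutamate transporter gene Slc17a6 (-0.74) were later. Foxa2, an endoderm regulator, was the only mesoderm and endoderm gene of 20 to pass over the list alone, from -0.98 ± 0.096 to -2.39 ± 0.30 (SD, n = 2), while Hand2 differed by -0.74 (trended and robust, 1 gene of the list was called earlier and 2 later). Among 72 ribosomal protein genes the only such gene was Rpl34, with -1.33, which lies in an early-to-late region, and Rpl23a differed by 0.99; with the trended, robust variance 6 ribosomal protein genes were called later and 0 earlier (limma, 11 at an unadjusted p under 0.05). Mest, Ddc, Zic1, Ptn and Slc17a6 lie outside the fixed rule and were named after their values were seen, because they make up these counts.

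The only list-level call was in a late-replicating receptor family, the vomeronasal receptors, and it depended on the test. The 265 vomeronasal receptor genes had a median difference of 0.14. Their adjusted p in limma's camera was 0.00385 at a preset correlation of 0.01 and 0.73 with an estimated correlation. The estimate for this list, 0.0053, was below the preset value, so a higher correlation does not account for the larger p. In the simulated list, whose genes varied independently, camera's adjusted p also differed between the 2 settings (0.184 estimated, 2.378e-15 preset). No single member passed in limma (40 at an unadjusted p under 0.05, 8 with a trended, robust variance). Over all 21078 genes these limma counts were 3610 and 1119, in each case a larger share than in this list. The largest differences were at Vmn2r20 (1.13, or 0.66 without auxin replicate 1 and 0.69 without control replicate 2) and Vmn1r44 (1.06, or 0.63 without control replicate 2). The 1104 olfactory receptor genes had a median difference of 0.11 (adjusted p = 0.0662 preset, 0.913 estimated) and 0 passing members (206 unadjusted; 35 earlier and 12 later trended and robust), and Olfr43 and Olfr139 differed by 1.35 and 1.32.

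No other list passed either test, and no list beyond the imprinted, neural, mesoderm and endoderm, and ribosomal ones had a gene past the threshold over the list alone. The median difference was 0.25 for 12 genes of the 2-cell-like state (Tcstv1 0.81, Zfp352 0.67, or 0.42 without control replicate 1), -0.18 for 14 trophoblast genes (Prl2c2 -0.45, Esx1 -0.89, or -1.42 and -0.36 without control replicate 1 and 2), 0.13 for 14 fibroblast feeder markers (Col5a1 0.82, Thy1 -0.79), -0.14 for 67 histone genes (H1f0 0.92, H2bc1 -0.64) and 0.06 for 362 zinc finger genes (Zfp185 -1.35, Zfp973 -1.35, or -2.32 and -0.37 without control replicate 1 and 2). With the trended, robust variance Tcstv1 was called earlier in the 2-cell-like list and Col5a1 among the feeder markers, 8 zinc finger genes earlier and 10 later, and no trophoblast or histone gene (1 and 3 at an unadjusted p under 0.05). Zfp352, Prl2c2 and Zfp973 overlap no window and take the value of the nearest one. For feeder markers and pluripotency genes the median and the mean differed in sign (0.13 and -0.0066, and 0.11 and -0.0027). So did those of the origin and timing genes (0.03 and -0.05) and of the mesoderm and endoderm genes (0.06 and -0.04). With the estimated correlation, camera called 0 of the 16 lists, with adjusted p between 0.73 and 0.91. It gave 1 list an unadjusted p under 0.05 (the vomeronasal receptors, 0.0456). Camera with this setting also missed the simulated list shifted by 0.5 (adjusted p of 0.184), so its 0 calls say little about shifts of that size. Fry, limma's rotation test, also called 0 in its directional form. Its mixed form, which takes members that move either way, was not adjusted over the lists. Fry's unadjusted mixed p ran from 0.00066 for the olfactory receptors to 0.70 for the Hox genes. The directional result therefore does not speak to lists whose members move both ways.

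The list medians depended on single profiles. Leaving out a profile moved the median of each list except the vomeronasal receptors (0.13 to 0.19) by more than 1.5 times or past 0. Without auxin replicate 1, the median was -0.0055 for histone genes, -0.054 for trophoblast genes, 0.049 for CTCF and cohesin genes, -0.18 for protocadherins, 0.10 for imprinted genes (0.03 with all profiles), 0.15 for ribosomal protein genes (0.08 with all profiles), 0.025 for mesoderm and endoderm genes and -0.0063 for origin and timing genes. Without auxin replicate 2, it was -0.24 for histone genes, 0.15 for 2-cell-like genes, 0.16 for mesoderm and endoderm genes, 0.0080 for protocadherins, -0.0031 for imprinted genes, -0.031 for pluripotency genes, -0.038 for feeder markers, -0.030 for ribosomal protein genes and -0.0036 for origin and timing genes. Without control replicate 1, it was 0.033 for olfactory receptors, 0.033 for zinc finger genes, 0.033 for mesoderm and endoderm genes, -0.037 for protocadherins, -0.00019 for CTCF and cohesin genes (0.15 with all profiles), -0.060 for pluripotency genes, -0.030 for feeder markers, -0.022 for ribosomal protein genes and -0.096 for origin and timing genes. Without control replicate 2, it was -0.22 for neural genes (-0.13 with all profiles), -0.30 for trophoblast genes, 0.41 for 2-cell-like genes, 0.12 for zinc finger genes, -0.055 for histone genes, 0.26 for CTCF and cohesin genes, 0.16 for imprinted genes, 0.13 for mesoderm and endoderm genes, 0.037 for feeder markers and 0.11 for origin and timing genes.

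Shifts of whole timing classes can be read from these scores only in part, because quantile normalization gives all profiles the same distribution and so holds class medians close together. The median difference was 0.014 in 17138 early bins, 0.015 in 5044 middle bins and 0.016 in 25898 late bins. The early median was -0.0036 without auxin replicate 2, 0.0043 without auxin replicate 1 and 0.031 without control replicate 2, and the late median was -0.028, 0.029 and 0.037 without control replicate 1, auxin replicate 1 and control replicate 2. The exact two-sided permutation p was 1, 0.333 and 1, and 0.333 is the smallest that 2 against 2 profiles allow. By chromosome, the mean difference ran from -0.10 on chromosome 13 to 0.08 on chromosome 11. Auxin profiles were both above both controls on 6 chromosomes (2, 4, 7, 9, 11 and 19) and both below on 4 (3, 12, 13 and 18).

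Profiles of the same group resembled each other more than profiles of different groups. The root mean square difference over bins was 0.376 between auxin replicates and 0.467 between control replicates, against 0.529 to 0.552 for the 4 auxin-control pairs. Across bins, which are not independent, Pearson's r was 0.986, 0.978 and 0.969 to 0.972. The auxin profiles lay both above or both below the controls in 50.2% of bins, where chance gives 33.3%.

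Because CTCF marks many domain boundaries, the steepness of the transitions between early and late domains was compared. At 1556 transitions, the median slope was 8.40 ± 0.048 score units per Mb with auxin and 9.77 ± 0.45 without (SD, n = 2), a difference of -14.0%. The profiles stood at 8.36 and 8.43 with auxin and at 9.45 and 10.09 without, so the groups did not overlap. Of the transitions, 77.9% were less steep in the auxin mean. The median ratio of auxin to control slope was 0.855 over all transitions and below 1 on each of the 20 chromosomes, from 0.795 on chromosome 7 to 0.910 on chromosome 18. Both auxin profiles were less steep than both controls at 46.5% of transitions and steeper at 6.81%.

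The exact two-sided permutation p for the median slopes was 0.333, the smallest possible here. Limma called 0 single transitions, with 294 at an unadjusted p under 0.05, while with slopes taken over 400 kb in place of 200 kb the difference was -10.5% (-0.771 score units per Mb, against -1.37 over 200 kb), 75.6% of transitions were less steep and limma called 114 transitions, 107 of them less steep with auxin. Limma also called 2 and 12 transitions without auxin replicate 1 and without auxin replicate 2.

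**Figure D4:**
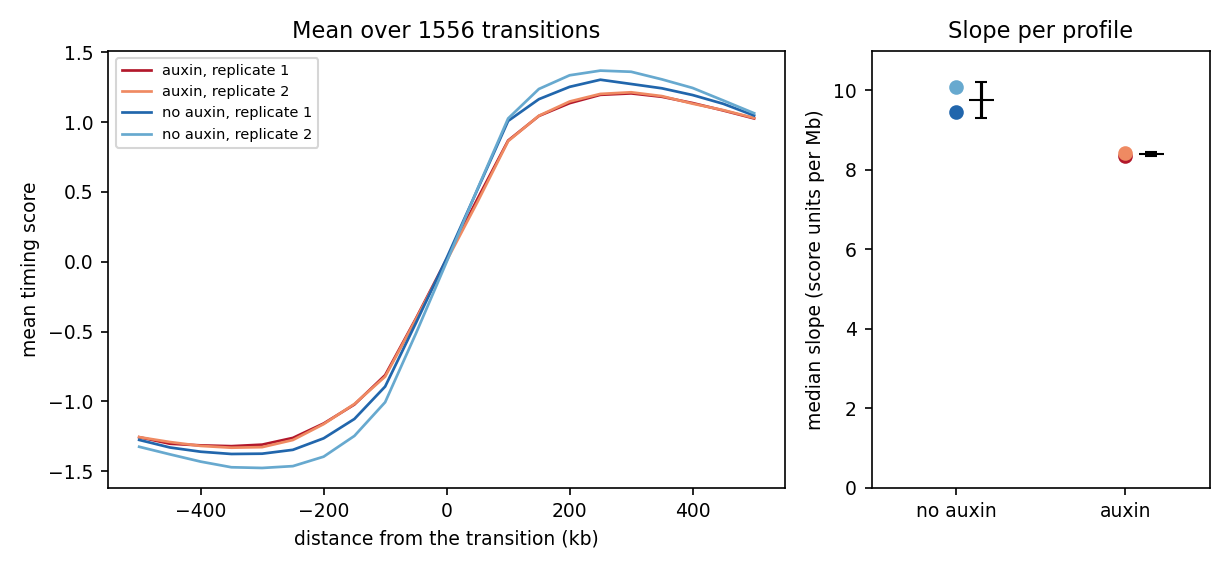
Left, the mean timing score (y axis, score units) of each profile against the distance from the transition (x axis, kb) over 1556 transitions turned to run from late to early. Right, the median slope of each profile (points, score units per Mb) with the group mean and SD (bars, n = 2), where the auxin profiles stand at 8.36 and 8.43 and the controls at 9.45 and 10.09.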

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

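Tests on bins or genes with at least 3 windows, the window nearest the middle of a gene, transitions picked in other profiles and the late-to-early list without 1 window were chosen after seeing the data. For the summary counts and values, single genes aside, 67 comparisons with an alternative left a result where it was, 25 brought it past a threshold or raised a count over 1.5 times, 2 lowered a count and 19 moved a value; none turned a direction called with all profiles. Between alternatives, a bin of 1 window on chromosome X (33900001 to 33950000) was called later without control replicate 1 (-22.82) and earlier without control replicate 2 (6.63). For 55 named genes, 4 of 569 comparisons turned the sign of a difference that had passed no test (Dppa2, Dppa4, Nanog and Pou5f1). Most of these comparisons could not turn a sign. Leaving out a profile cannot do so unless the groups overlap, which they did only at these 4 genes and Sox2. The scaling, autosome, variance, block and window-number settings leave the difference itself as it is. Rescaling and renewed quantile normalization changed nothing, which is no test, since the sorted columns are identical. Their comparisons are counted among the 67 and the 569. The fits fixed beforehand called 1 bin, 0 genes, 0 lists and 0 transitions, so few called directions could turn.

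The number of called bins, 1 over all bins, was 3164 with single windows, 0 on autosomes (8724 at an unadjusted p under 0.05; limma), 707 in bins with at least 3 windows, 3853 with a trended, robust variance and 4626 with both. Counted at a difference of 1 or more, these were 3164, 0, 654, 916 and 873. The autosomal count is 0 because the only called bin is on chromosome X; the other causes were not tested. With the replicate block, in which replicates of the same number are paired, 122 bins were called, all by 1 or more; the numbers did not pair the profiles otherwise (correlation of deviations 0.069). Leaving out a replicate gave 2 to 6 bins, namely 2 without either auxin replicate, 3 without control replicate 1 and 6 without control replicate 2; the lone profile is assumed to vary like the other group.

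Called genes, 0 over all genes, were also 0 among the 12984 with at least 3 windows (limma, smallest adjusted p of 0.0755). With a trended, robust variance they were 1119 over all genes and 1391 with at least 3 windows besides. Leaving out a replicate gave 0 to 1 genes; the 1 gene, Btbd35f6, came without control replicate 1 and rests on a window at the table's maximum, 23.35, in control replicate 2. Camera called 1 list with the preset correlation. The cause was not tested for the variance settings. For the list settings, only a higher estimated correlation was set aside, since that list's estimate of 0.0053 was below the preset 0.01.

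The middle class's median difference was 0.0078 with limits of 1 and -1 and 0.0116 on autosomes. Without a replicate, the early class ranged from -0.0036 (without auxin replicate 2) to 0.031, the middle class from 0.0106 to 0.0172 and the late class from -0.028 (without control replicate 1) to 0.037. The slope difference, -1.37 over 200 kb, was -0.771 over 400 kb (-10.5% against -14.0%), -1.73, -1.15, -1.77 and -1.04 in transitions picked in other profiles, and -1.69 to -1.05 without a replicate. Called transitions numbered 114 over 400 kb and 0 to 12 without a replicate (12 without auxin replicate 2, 2 without auxin replicate 1). The cause was not tested.

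In the authors' lists, the share of covered bins called over all bins was 1.47% for the late-to-early list, 1.22% with any overlap and 1.72% with stricter regions. Each of these shares is the 1 called bin on chromosome X, which rests on the extreme window. In bins with at least 3 windows it was 78.1%, 75.6% and 83.3%, and for the early-to-late list 88.5%, 79.2% and 88.1%. The late-to-early mean was 1.27 in stricter regions and 1.18 without the extreme window on chromosome X. The start of transcription was not used for gene values, because the gene table has no strand. Depth is unknown, so which windows rest on few reads could not be told.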

Other observations

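Runs of called bins also lay outside the authors' lists, 159 of the 175 earlier runs and 175 of the 220 later ones, in bins with at least 3 windows. Those of 3 or more bins, 7 earlier and 13 later, were chosen after their values were seen. On chromosome 16 (78250001 to 78400000), Cxadr, a cell adhesion receptor gene, and the antiproliferation gene Btg3 went from 0.79 ± 0.30 to -0.46 ± 0.063 (SD, n = 2). The methyl-CpG-binding gene Mbd2 on chromosome 18 (70550001 to 70700000) went from 0.93 ± 0.14 to -0.19 ± 0.019, and the centromere protein gene Cenpc1 with Stap1 on chromosome 5 (85950001 to 86100000) from 0.43 ± 0.0029 to -0.69 ± 0.11. Earlier runs covered Fstl4 on chromosome 11 (52800001 to 53000000), from -0.57 ± 0.12 to 0.53 ± 0.067, and the growth factor gene Ptn with the kinase gene Dgki on chromosome 6 (36800001 to 37000000), from -0.72 ± 0.070 to 0.33 ± 0.049.

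Local extremes of timing were compared with their surroundings of 1 Mb. They were picked on the mean of all 4 profiles, and no sets picked and measured in different profiles were made, so an effect of picking on noise was not tested here. In 3671 bins that replicated 1 or more earlier than their surroundings, the median contrast was 1.19 in both auxin profiles and 1.36 and 1.47 in the controls. In 2917 bins that replicated 1 or more later, it was -1.11 and -1.14 with auxin and -1.25 and -1.46 in the controls, so the control profiles lay further apart there than control replicate 1 lay from either auxin profile.

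The tests of picking on noise and of added noise at transitions, and both tests of the region on chromosome X, were chosen only after the result was seen; the tests of blurring were chosen before.

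Transitions were less steep with auxin (8.40 against 9.77 score units per Mb). Picking transitions by their slope favours noise in the profiles used, so transitions were also picked in 1 profile of each group and measured in the other 2; the lowest share less steep with auxin was 0.6614 in these sets, which argues against picking on noise as the whole cause. Quantile normalization could turn added noise into lower contrast. The auxin profiles differed less from each other than the control profiles did on 20 of 20 chromosomes. All chromosomes come from the same profiles, so this compares 1 pair of replicates with 1 other pair. The control profiles also differed in median slope (9.45 and 10.09), which may add to the difference between them. Noise shared by the auxin replicates would not raise the difference between those replicates. The comparison therefore cannot exclude added noise. Uniform blurring along the genome, from sorting or smoothing, cannot be told apart from a local effect: smoothing 1 control profile changed bins in a way that correlated at 0.104 and 0.111 with the difference of auxin from the other control. A loss of sharp domain edges without CTCF may also underlie the slopes, and stays open beside added noise and a difference in sorting between groups.

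Uniform blurring was also tested for the authors' regions. Control profiles were smoothed by a Gaussian with an SD of 55 or 75 kb until their slopes met those with auxin, and 71 of 85 regions still differed by 1 or more from them. The median difference went from -1.27 to -1.19 in early-to-late and from 1.18 to 1.12 in late-to-early regions, so blurring alone is an unlikely cause of these differences. The regions were chosen on these samples for differing, and whether loss of CTCF at their own sites accounts for them was not tested.

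The late-to-early region of 2952 kb on chromosome X may owe its place in the list to 1 window. Without the window at 126240000 its difference was 0.303 instead of 1.60. The other 22 windows had a median difference of 0.2854 with an SD of 0.305, and 1 of them reached 1, which argues against a shift of the whole region by the listed amount. That 20 of the 22 lay above 0 leaves a smaller shift open.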
